A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

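The series measured transcript levels in a wsc1 mutant of Saccharomyces cerevisiae on 4 two-channel DNA microarrays, each of which compared RNA of cells grown with Congo Red against RNA of cells grown without it. Per the labels, each array received Cy5- and Cy3-labelled cDNA made by reverse transcription of total RNA, with Congo Red RNA in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. The design text gives 2 cultures and a dye swap for each, but which arrays share a culture is not given in the sources used here. The labels and the design text also differ in how long the cultures grew before Congo Red was added.

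The deposited table holds 1 log ratio per reading frame and array, read here as log2; the authors' log base, numerator, centring, background correction and normalization are not given in the sources used here, nor is the scanner, the kind of probe or the rule by which cells were left empty. Signal over background cannot be seen in a table of ratios. The table has 6209 rows, of which 2 name control spots and were left out, which leaves 6207 reading frames. A symbol was found for 5654 of them by systematic name in the RefSeq gene table of the yeast S288C assembly R64, and the other 553 keep the systematic name. No coordinates are given because no source names the build of the array design.

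Array medians were -0.14, -0.14, -0.11 and -0.08 log units for arrays 1 to 4, with SDs of 0.52, 0.51, 0.48 and 0.33. Empty cells made up 47.6, 42.0, 31.2 and 19.6% of the reading frames. The 3080 reading frames with a value on all 4 arrays were tested, and values were used as deposited, with no further normalization. Array number limits the precision: the independent units are 2 cultures.

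Before the data were examined, the tests, the threshold, the gene lists, the rule for naming genes and most alternatives were fixed. The replicate is the culture, so the 2 arrays of opposite dye from a culture were averaged, which cancels a constant dye effect. Only 2 pairings of the arrays give each culture both orientations (1 with 2 and 3 with 4, or 1 with 4 and 2 with 3). Each gene was fitted under both with limma 3.58.1 (lmFit and eBayes, intercept only) in R 4.3.3, the larger p was kept, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. SE is the larger of the moderated standard errors of the 2 pairings, with n = 2 cultures. It draws in part on the variance pooled over all genes. An SE of 0.09 is close to the lowest that this fit can give and does not measure the spread between a gene's own 2 cultures. Adjusted p-values of single genes come from this limma fit, two-sided. A dye effect was tested with limma on the 4 arrays with a term for dye orientation. Gene lists with at least 5 tested members were compared with all other genes by limma's camera under both pairings. The preset correlation between genes was 0.01, the larger p was again kept, and an estimated correlation was tried next. From 2 culture means that correlation can hardly be estimated, so its p-values cannot decide whether a list shifted. A list's shift is the mean of its members minus the mean of all other tested genes.

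The direction of the ratios was settled only in part by the rule fixed beforehand. That rule read arrays of opposite orientation as already turned by the submitters if their values correlated above 0.3 across genes, and as channel ratios if below -0.3. The mean Pearson r across genes was 0.10, which lies between the limits, so the rule gave no direction. Spearman correlations of these arrays ran from -0.26 to 0.10, also between the limits. Reading the values as already turned, with Congo Red as the numerator, was chosen after the data were seen. Of 26 measured targets of the cell wall integrity pathway, 22 lay above 0 on all 4 arrays, against 1 with a single sign if arrays 2 and 4 are turned. Of 21 reading frames with a size of at least 1 log unit on every array, 15 had a single sign and 0 had opposite signs by dye orientation. The overall sign was set, as planned, so that the median of these targets is above 0. The direction is therefore called likely. The direction, the size of the shift and the p-values of this list are no independent result. The same holds for lists through the members they share with it.

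Named genes are the 12 with the largest increase and the 12 with the largest decrease among genes past the threshold with a single sign on all arrays, up to 4 members per list (those past the threshold with the largest change, or otherwise the 2 largest as values), and WSC1, MID2, SLT2 and RLM1. Other genes named were chosen after their values were seen, and the text says so or gives them as members of a list. The result of 1 list that camera called is not reported here, though it is part of the counts of lists.

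The fits were tested on simulated data, in 10 runs of 3080 genes for the comparison of Congo Red against untreated. Gene variances were drawn from the distribution fitted to the real arrays, and the dye effects were shuffled between genes. All arrays had the same spread, a share of 0.5 of the variance was common to a culture, and arrays 1 and 2 formed a culture. Of genes changed by 0.5, 1 and 2 log units, 22.7, 92.2 and 99.4% were called, and 5.75% of the calls were false. Unchanged genes were simulated around 0, whereas the real tested genes had a median of -0.10. The share of false calls therefore need not hold for the real data, above all for the decreases. Of 10 simulated lists that moved by 0.5, 10 were called, and 0 of 200 unmoved lists were. Simulated genes varied independently, so these counts do not show how often a list of co-regulated genes would be called by mistake.

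The alternatives tried were each pairing alone, the 4 arrays as replicates with and without a dye term, centring each array on its median, scaling arrays to a common median absolute value, genes with a value on at least 3 arrays, robust eBayes, an adjusted p below 0.1, ranks in camera, an estimated correlation and leaving out each array. Turning arrays 2 and 4, leaving out Ty element rows and leaving cell wall integrity targets out of the other lists were added after the data were seen.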

Results

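Transcripts were measured in budding yeast (Saccharomyces cerevisiae, BY4741 background) with a mutation of WSC1, the gene of a plasma membrane sensor of cell wall stress. Congo Red is a dye that binds chitin and glucan and disturbs assembly of the wall. Cultures were split at 24 °C, 1 part received Congo Red at 30 µg/ml, and cells were collected at 4 h. RNA of the treated and untreated part was hybridised together, so each of the 4 arrays gives a log ratio per gene from 1 of 2 cultures. Of 6207 reading frames, 3254, 3602, 4273 and 4991 had a value on arrays 1 to 4, and the 3080 with a value on all 4 arrays (49.6%) were tested. The WSC1 row (YOR008C, listed as SLG1) was empty on all 4 arrays, so the mutation could not be checked on its own transcript. No strain with an intact WSC1 gene was used here, so the values describe the response of the mutant alone.

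The comparison asks which transcripts of the mutant differ with Congo Red. Genes of the cell wall and of its integrity pathway led the increases. NCW2 (YLR194C), which codes for a wall mannoprotein, rose by 3.30 ± 0.09 log units (moderated SE, n = 2 cultures, adjusted p = 0.0016). This is 9.85-fold if the log base is 2. PRM5 (YIL117C), a membrane protein gene under cell integrity signalling, rose by 3.17 ± 0.09 (adjusted p = 0.0016), and CRG1 (YHR209W), coding for a methyltransferase, by 2.76 ± 0.11 (adjusted p = 0.00392). SLT2 (YHR030C), the gene of the MAP kinase of the cell wall integrity pathway, rose by 1.30 ± 0.12 (adjusted p = 0.0198). The largest decrease with a single sign on all arrays was that of SOL4 (YGR248W), a 6-phosphogluconolactonase gene, at -1.65 ± 0.12 (adjusted p = 0.0167).

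These signs are likely rather than settled. The sources state neither the numerator nor the log base, and the ratios were read as Congo Red over untreated because 22 of 26 measured cell wall integrity targets lay above 0 on all 4 arrays. If the numerator were the untreated part, every direction given here would swap. If arrays 2 and 4 had been left as channel ratios and are turned, limma on culture means calls 0 genes in place of 80. Then 857 pass an unadjusted p below 0.05. That contrast depends on the fit, since turning makes a gene's dye effect its Congo Red effect. Limma on the 4 arrays with a dye term called 493 genes for the dye effect and 320 for Congo Red.

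Congo Red changed 80 of the 3080 genes, with 47 higher and 33 lower, and 807 passed an unadjusted p below 0.05. The increases were larger, with a median of 1.08 log units against -0.81 for the decreases. All 4 arrays had a single sign for 78 of the 80, the exceptions being YNR014W and OXA1. A mean of at least 1 log unit with a single sign on all arrays was found for 30 genes, 27 above 0 and 3 below, and 28 of these were among the called genes. The median of all tested genes was -0.10, and centring each array on its median moved the median by 0.12. After centring 32 genes were called, 30 higher and 2 lower (SOL4 and YNR014W), so the share of higher genes went from 58.8% to 93.8%. Other fits moved this share either way. It fell with 121 higher and 199 lower for 4 arrays with a dye term, 255 and 532 with arrays 1 and 4 as a culture, and 58 and 62 after scaling. It rose with 28 and 8 for 4 arrays without a dye term, and 17 and 2 when values on 3 arrays sufficed. All 33 lower genes still lay below 0 after centring, with a median of -0.69. No called gene lay nearer to 0 than 0.62 before it, so centring could not turn a sign. Leaving out an array needs another fit, limma on single arrays with a dye term. Without array 2 or 4 each gene's own noise comes from arrays 1 and 3 alone, and without array 1 or 3 from arrays 2 and 4 alone. A call lost this way need not rest on the array left out. With all 4 arrays this fit called 320 genes, the 80 among them. That fit called 375, 13, 823 and 25 genes without arrays 1, 2, 3 and 4. Of 40 named genes that were called, 13 stayed called whichever array was left out, 27 lost the call without array 2 and 22 without array 4. The 13 are NCW2, PRM5, CRG1, YEL074W, NFG1, YPS3, PUN1, PST1, CRH1, NCE103, GFA1, CWP1 and SOL4.

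**Figure D1:**
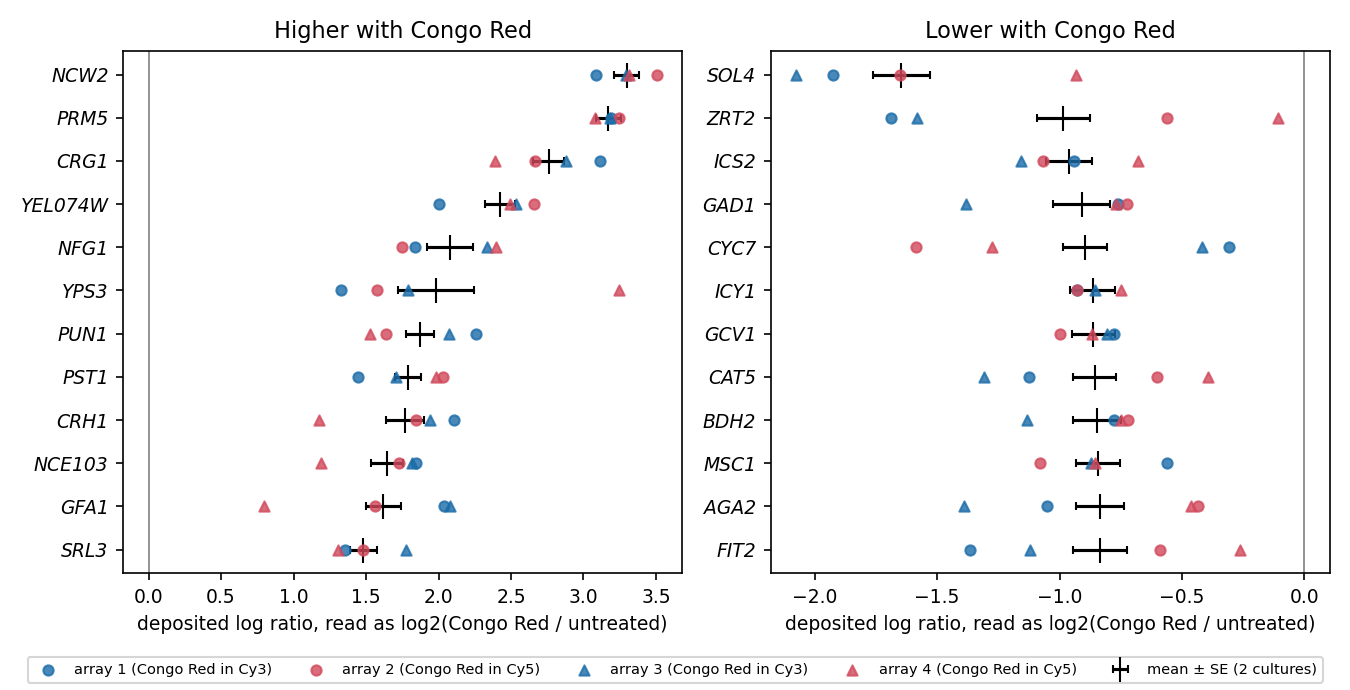
Deposited log ratios on each array (horizontal axis, log units, read as log2 of Congo Red over untreated) for the 12 genes with the largest increase and the 12 with the largest decrease, among genes past the threshold with a single sign on all arrays. Colour gives the dye of the Congo Red RNA. Bars give the mean ± moderated SE (n = 2 cultures), which draws in part on the variance pooled over all genes. NCW2 and PRM5 lie near 3 on all 4 arrays, while ZRT2 ranges from -1.69 on array 1 to -0.11 on array 4.

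Of the remaining genes with the largest increases, YEL074W, an unnamed reading frame, rose by 2.42 ± 0.10 (adjusted p = 0.00392), and NFG1, linked to filamentous growth, by 2.08 ± 0.16 (adjusted p = 0.0173). YPS3, coding for a yapsin protease of the cell surface, rose by 1.98 ± 0.27 (adjusted p = 0.0478), with 3.24 on array 4 and 1.33 to 1.79 on the others, and was not called after centring. PUN1, coding for a plasma membrane protein, and PST1, coding for a wall protein, rose by 1.87 and 1.79 (adjusted p = 0.00751 for each). CRH1, coding for an enzyme that links chitin to glucan, rose by 1.77, and GFA1, coding for the enzyme that commits sugar to chitin precursors, by 1.62. NCE103, the carbonic anhydrase gene, rose by 1.64 and SRL3 by 1.48.

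The list of 31 cell wall integrity targets was fixed beforehand. Of its 26 tested members, 20 rose, 0 fell and 6 were not called, and 23 passed when p-values were adjusted over the list alone. Its mean lay 1.36 log units above that of all other genes (camera, adjusted p = 1.15e-24; adjusted p = 0.843 with an estimated correlation). Beside the genes above, the wall protein genes CWP1, PIR3 and SED1 rose by 1.44, 1.32 and 1.08, and SED1 was not called after centring. PIR1 at 0.77, the mannosyltransferase gene KTR2 at 0.39 and the chitin synthase gene CHS3 at 0.03 were not called. Because the sign of the ratios was set on this list, its direction is not independent evidence.

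Of 27 tested genes of glucan and chitin synthesis and remodelling, 6 rose, 0 fell and 21 were not called. The list shifted up by 0.36 (adjusted p = 0.000381; adjusted p = 0.843 with an estimated correlation), and 12 passed when adjusted over the list alone, 10 above 0 and 2 below. The genes that rose were CRH1, GFA1, GSC2, PCM1, CHS7 and BGL2. PCM1, which acts after GFA1 in making the chitin precursor, rose by 0.96 ± 0.09 (adjusted p = 0.0273), CHS7, needed for export of chitin synthase, by 0.83 ± 0.09 (adjusted p = 0.0325), and GSC2, a glucan synthase subunit, by 0.82 ± 0.12 (adjusted p = 0.0476). PCM1 and CHS7 were not called after centring. FKS1, the other glucan synthase gene, was at 0.34 and the septum gene SUN4 at -0.47, neither of them called. Without the 4 members that are also cell wall integrity targets, the other 23 still shifted up by 0.23 (adjusted p = 0.014; adjusted p = 0.89 with an estimated correlation).

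Of 18 tested structural wall proteins, 6 rose, 0 fell and 12 were not called, and 10 passed when adjusted over the list alone, 8 above 0 and 2 below. The list shifted up by 0.43 (adjusted p = 0.000903; adjusted p = 0.843 with an estimated correlation). The genes that rose were PST1, CWP1, PIR3, SED1, CIS3 and HSP150. Without 7 members that are also cell wall integrity targets, the other 11 gave a shift of -0.08 and no call (adjusted p = 0.976).

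Of 12 tested components of the cell wall integrity pathway, SLT2 and the sensor gene MID2 rose, by 1.30 and by 1.14 ± 0.09 (adjusted p = 0.0186), and 10 were not called. The kinase genes PKC1 and BCK1 were at -0.20 and 0.06, and the GTPase gene RHO1 at 0.44. RLM1, the gene of the transcription factor below SLT2, had values on arrays 3 and 4 alone, 0.05 and 0.01. The list shifted up by 0.36 with a median of 0.02 (adjusted p = 0.0327; adjusted p = 0.843 with an estimated correlation), and 3 passed when adjusted over the list alone. The call was lost after centring (adjusted p = 0.0623), without array 2 (adjusted p = 0.0747), with ranks (adjusted p = 0.0848) and without the 2 members shared with the target list (adjusted p = 0.113).

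Of 9 tested calcineurin and Crz1 targets, GSC2 rose and 8 were not called, while 4 passed when adjusted over the list alone, all above 0. RCN2, a calcineurin regulator, and PHO89, a phosphate transporter, were each at 0.54. The list shifted up by 0.34 (adjusted p = 0.00386; adjusted p = 0.843 with an estimated correlation), and without GSC2 by 0.27 (adjusted p = 0.0204; adjusted p = 0.89 with an estimated correlation).

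**Figure D2:**
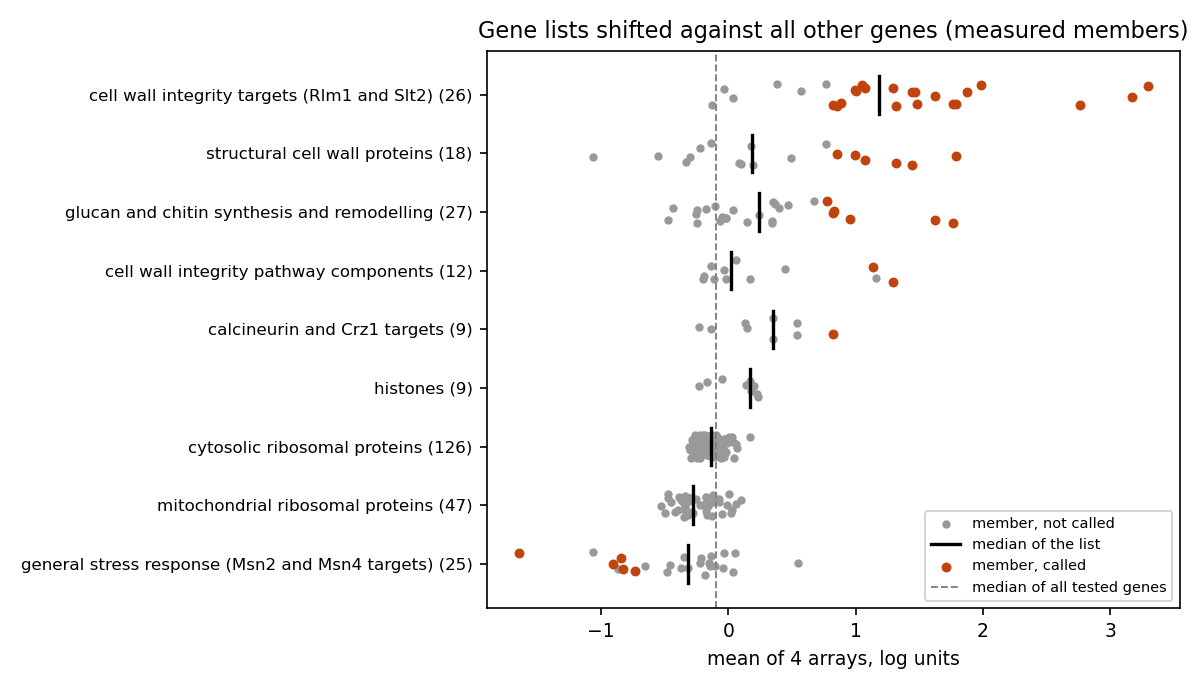
Mean log ratio over 4 arrays (horizontal axis, log units) of each tested member of 9 lists that camera called with a preset correlation, with the number of tested members in brackets. Orange points are members called by limma, grey points are not called, black bars are list medians and the dashed line is the median of all tested genes (-0.10). The cell wall integrity targets have a median of 1.19 and the general stress genes one of -0.32.

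The list of general stress genes, which the Msn2 and Msn4 factors drive, shifted down by a value of -0.35 (adjusted p = 0.00273; adjusted p = 0.843 with an estimated correlation). Of 25 tested members 5 fell, 0 rose and 20 were not called, and 11 fell when adjusted over the list alone. After SOL4, the members that fell were GAD1, the glutamate decarboxylase gene, at -0.91 ± 0.12 (adjusted p = 0.0476) with -1.38 on array 3, MSC1 at -0.84 ± 0.09 (adjusted p = 0.0286), DCS2, linked to decapping of mRNA, at -0.83 ± 0.09 (adjusted p = 0.031) and PGM2, the phosphoglucomutase gene, at -0.73 ± 0.09 (adjusted p = 0.0476). HSP12 at -0.03 and HSP26 at -0.19, small heat shock protein genes, were not called. Of the 5 genes SOL4 alone was called after centring, at -1.53. Of 10 tested trehalose and glycogen genes PGM2 alone fell over all genes. Adjusted over that list alone 3 fell, with TSL1 at -0.65 and UGP1 at -0.48 beside PGM2. Of 21 heat shock proteins and chaperones 0 were called over all genes or over the list alone.

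Respiratory chain genes were not shifted as a list of 30, but CYC7 and COX5B fell. These code for the forms of cytochrome c and of a cytochrome oxidase subunit used at low oxygen, and were at -0.90 ± 0.09 (adjusted p = 0.0273) and -0.63 ± 0.09 (adjusted p = 0.0498). Their counterparts CYC1 and COX5A were at -0.25 and -0.26 and were not called. CAT5, needed to make ubiquinone, fell (-0.86 ± 0.09, adjusted p = 0.0273). In the tricarboxylic acid cycle list of 19, CIT2, coding for the peroxisomal citrate synthase, rose by 0.89 ± 0.09 (adjusted p = 0.0273), and the list, with a shift of 0.18 and a median of -0.04, was not called (adjusted p = 0.0547), though it was without array 3 or array 4 (adjusted p = 0.034 and 0.0258). MET14 rose by 0.88 ± 0.09 (adjusted p = 0.0273) within a sulfur list that was not called, with a shift of 0.01 but a median of -0.16 and a downward camera direction (adjusted p = 0.904). From the amino acid list LEU1 fell (-0.66 ± 0.09, adjusted p = 0.0478). GCV1, coding for a subunit of glycine decarboxylase, fell (-0.86 ± 0.09, adjusted p = 0.0273). After centring CIT2 and MET14 were still called, and CYC7, COX5B, CAT5, LEU1 and GCV1 were not.

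Of 12 tested mating genes, 3 fell and 0 rose. The agglutinin subunit gene AGA2 was at -0.83 ± 0.10 (adjusted p = 0.0353), the pheromone gene MFA2 at -0.66 ± 0.09 (adjusted p = 0.0476) and the pheromone receptor gene STE2 at -0.64 ± 0.09 (adjusted p = 0.0498). Over the list alone 5 fell, and the list's shift of -0.23 was not called (adjusted p = 0.185). In the iron list of 13, FIT2, coding for a wall protein that holds siderophores, fell (-0.83 ± 0.11, adjusted p = 0.0476), while FET3 at -0.66 was not called. Among genes in no list, ZRT2, ICS2, ICY1 and BDH2 fell. The zinc transporter gene ZRT2 was at -0.99 ± 0.11 (adjusted p = 0.0315), ICS2 at -0.96 ± 0.10 (adjusted p = 0.0264), ICY1 at -0.86 ± 0.09 (adjusted p = 0.0297) and the dehydrogenase gene BDH2 at -0.85 ± 0.10 (adjusted p = 0.0351), with -1.13 on array 3. None of these 8 decreases was called after centring, a step too small to turn the sign of their means.

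Ribosomal protein and histone lists shifted without a called member. The 47 mitochondrial ribosomal proteins shifted by -0.18 (adjusted p = 0.00182; adjusted p = 0.843 with an estimated correlation), with MRPL8 at -0.53 and MRP35 at -0.50. The 126 cytosolic ribosomal proteins shifted by -0.08 (adjusted p = 0.00999; adjusted p = 0.843 with an estimated correlation), a call that was lost after centring (adjusted p = 0.103), with ranks (adjusted p = 0.0588) and without array 3 (adjusted p = 0.105). The 9 histone genes shifted by 0.14 (adjusted p = 0.0459; adjusted p = 0.843 with an estimated correlation), with HHT1 at 0.23 and HTZ1 at -0.23 (-1.16 on array 2), and that call was lost after centring (adjusted p = 0.0707), after scaling (adjusted p = 0.0579) and without arrays 1, 3 or 4 (adjusted p = 0.0795, 0.164 and 0.15). Adjusted over their lists alone, 0 ribosomal protein and 0 histone genes passed.

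Camera called 10 of the 32 tested lists, 6 up and 4 down, and 0 with an estimated correlation on the culture means, where 0 had an unadjusted p below 0.05. On the 4 arrays with a dye term and an estimated correlation, again 0 lists were called and 2 had an unadjusted p below 0.05. So few arrays leave almost no residual information for an estimated correlation, which thus cannot decide whether a list shifted. Even the cell wall integrity targets, shifted by 1.36, had an unadjusted camera p of 0.18 on the culture means. The other 22 lists were not called, 15 of them without any called member. They include ribosome biogenesis, with BMS1 at 0.68 and SPB1 at 0.52 (list adjusted p = 0.0774). Camera called that list on 4 arrays with a dye term (adjusted p = 0.0332), with arrays 1 and 2 as a culture (adjusted p = 0.026) and with ranks (adjusted p = 0.0408). Its shift of 0.09 was 0.03 without array 3 and 0.14 without array 1. Others among the 22 are endoplasmic reticulum folding, with HAC1 at 0.73 and SCJ1 at 0.54 (adjusted p = 0.154), and the osmotic stress list (adjusted p = 0.101), with MSB2 at 0.77 and YPD1 at 0.46. MSB2 was at -1.24 on array 3. Without that array, limma on single arrays with a dye term gave 1.35. The fit on culture means, with all 4 arrays, did not call MSB2 (adjusted p = 0.263). YPD1 had a called dye effect (adjusted p = 0.0222), with 1.07, -0.06, 0.94 and -0.10 on arrays 1 to 4, and was called in the fit to single arrays with a dye term (adjusted p = 0.0217), also without array 1 (adjusted p = 0.0187) or array 3 (adjusted p = 0.00454). Proteasome genes RPN7 and RPN4 had means of 0.36 and 0.34 (list adjusted p = 0.0618, but 0.0136 after centring), but the sign of RPN4 followed the dye, with 1.13, -0.34, 0.83 and -0.28 on arrays 1 to 4 (adjusted p = 0.0218 for the dye effect) and a call without array 3 (adjusted p = 0.0135). RPN7 was called in the fit with a dye term (adjusted p = 0.0413), also without array 1 (adjusted p = 0.0416) or array 3 (adjusted p = 0.0317). Ergosterol, Pho4, Yap1 and drug resistance genes led with ERG10 at 0.52, PHO12 at -0.60, SOD1 at -0.49 and IPT1 at 0.45, none of them called. Lists of genes of G1 and S phase, of G2 and M phase and of glycolysis gave adjusted p-values of 0.904, 0.253 and 0.651, with TOS4 at -0.42, CLB1 at -0.33 and ADH1 at -0.45. The list of alpha cell and meiosis genes was not tested, since 1 of its 20 members had a value on all 4 arrays, ZIP1 at 0.01.

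The dye swap also gives the part of each ratio that follows the dye. Limma on the 4 arrays with a dye term called a dye effect for 493 genes (16.0%), of which 251 had higher ratios with Congo Red RNA in Cy3 and 242 with it in Cy5. Of the 80 genes changed by Congo Red, 21 were among them. DDR48 lay at 1.47 and 2.17 on arrays 1 and 3 and at 0.01 and 0.02 on arrays 2 and 4, with a mean of 0.92 (adjusted p = 0.0476), and its reading frame overlaps that of YMR173W-A. YNR014W lay at -2.44 and -2.64 on arrays 1 and 3 and at -0.34 and 0.17 on arrays 2 and 4. ZRT2, CYC7, CAT5, AGA2, FIT2, DCS2 and CIT2 also had a called dye effect. Arrays of the same orientation correlated across genes with Pearson r = 0.64 for arrays 1 and 3 and 0.71 for arrays 2 and 4. For arrays of opposite orientation Pearson r was -0.05 to 0.33 and Spearman correlation -0.26 to 0.10, and genes are not independent replicates. When array 2 or 4 is left out, each gene's own noise in the dye fit comes from arrays 1 and 3 alone. Without array 2 or without array 4, limma called a dye effect for 0 and 1 genes, with 747 and 728 at an unadjusted p below 0.05.

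**Figure D3:**
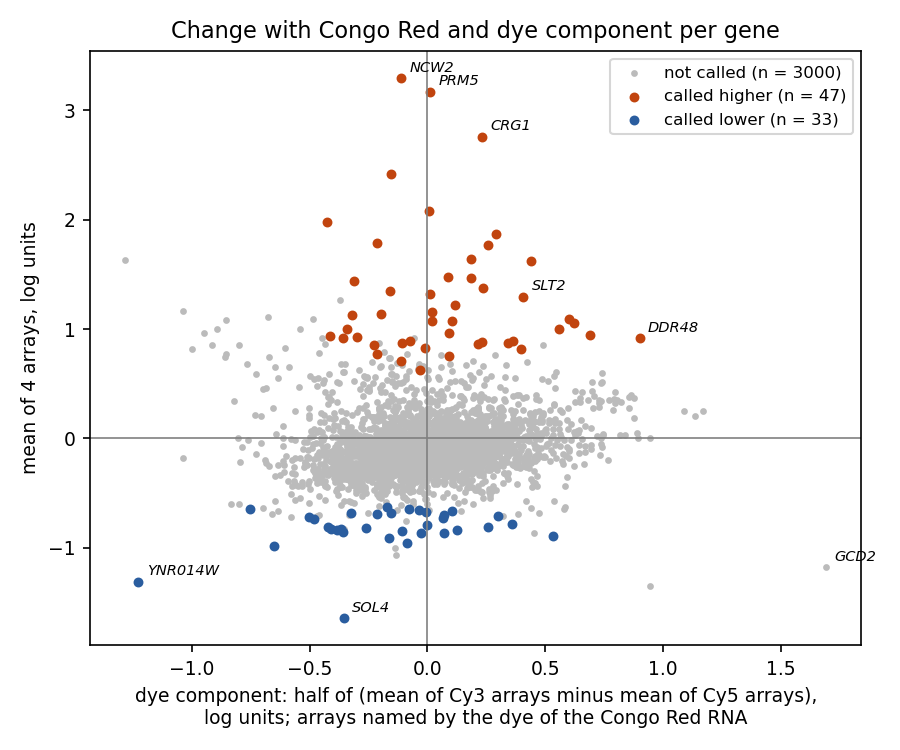
Mean log ratio over 4 arrays (vertical axis, log units) against the dye component of each tested gene (horizontal axis, log units). Orange points are the 47 genes called higher, blue points the 33 called lower and grey points the 3000 not called. NCW2 and PRM5 have a small dye component, while DDR48 and YNR014W lie far from 0 on both axes, and GCD2 lies low through its value on array 2.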

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

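The comparison of turned and unturned ratios and the correlation of dye components were chosen after the result was seen.

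A single array stood apart from the other 3, by Dixon's ratio of gap to range, for 5 of the 79 named genes. For 4 independent values of a normal distribution, chance would give about 3.95. The arrays differ in spread and many genes have a dye effect, so that rate need not hold here. GAD1 was at -1.38 on array 3, against a median of -0.76 on the others. BDH2 was at -1.13 on array 3, against -0.75. PGM2 was at -0.51 on array 1, against -0.80. The histone variant gene HTZ1 was at -1.16 on array 2, against 0.15. GCD2, a translation initiation factor gene, was at -5.92 on array 2, against 0.35, and its mean of -1.18 rests on that value.

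Many genes gave different ratios on arrays of opposite dye orientation, 493 of them past the threshold. A candidate explanation is that the deposited ratios were never turned to a common direction. The median of the cell wall integrity targets, 1.19, came down to 0.050 when arrays 2 and 4 were turned. The reading of the ratios was chosen on these same targets, so this is no independent test and cannot decide the question. Gene-specific dye bias cannot be told apart from other effects of the orientation: the difference between array 1 and array 2 correlated across genes with that between array 3 and array 4 at r = 0.71, but the 493 calls already need a difference that repeats, so this adds no evidence. No biological explanation was tested, since the swap compares the same RNA in both dyes.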

How the results depend on the processing

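Turning arrays 2 and 4, leaving out Ty element rows and leaving cell wall integrity targets out of the other lists were chosen after the data were seen; the remaining alternatives were planned. Counts of changed genes, against 80 (47 higher, 33 lower), were 787 (255 higher, 532 lower) with arrays 1 and 4 as a culture, 320 (121 and 199) with 4 arrays and a dye term, 36 (28 and 8) without that term, 32 (30 and 2) after centring, 19 (17 and 2) when 3 arrays sufficed, 214 (100 and 114) at an adjusted p below 0.1, and 122 (63 and 59) without Ty rows. Scaling gave 120, of which 62 were lower. With arrays 2 and 4 turned, limma on culture means called 0 genes, 0 higher and 0 lower (857 at an unadjusted p below 0.05). Turning makes a gene's dye effect its Congo Red effect, and limma on 4 arrays with a dye term called 493 dye effects. All 80 genes were among those called with a dye term and without Ty rows, and all 32 called after centring were among the 80. Without 1 array, in the fit with a dye term that gave 320, the counts were 13 to 823 (without arrays 2 and 3; 375 and 25 without arrays 1 and 4), 12 to 263 higher and 1 to 560 lower. Genes of at least 1 log unit with a single sign, 30, became 123 at 1.5-fold, 15 when each array had to pass, 4 with arrays 2 and 4 turned, and 31 to 65 without 1 array. Called lists, 10, became 0 with an estimated correlation, on culture means and on 4 arrays alike. That setting cannot decide whether a list shifted, since so few arrays hardly allow it a call. Under the other settings 7 to 12 lists were called. Dye calls, 493, ranged from 0 to 661 without 1 array. A looser threshold raises these counts by construction. Leaving out array 2 or 4 leaves arrays 1 and 3 as the only source of each gene's own noise, and leaving out array 1 or 3 leaves arrays 2 and 4. Whether this or the array left out moved the counts was not tested, nor was the cause for the other settings. None of the 40 called named genes changed sign in any setting run for single genes (centring, scaling, a dye term, 1 array left out). All 40 had a single sign on all 4 arrays, and centring was too small a step to turn a sign. That outcome was thus fixed in advance and is no evidence of stability. Testing several probes per gene could not be run, as each reading frame has 1 value per array. No paired analysis was possible beyond the fits above, because each log ratio is already the difference of treated and untreated RNA within a culture. Signal over background is unknown here, and empty cells left 3080 of 6207 reading frames for the tests.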

Other observations

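The tests of the Ty rows and the glucose hypothesis were chosen after the result was seen, as were the genes named in the next 2 paragraphs; the tests of an array offset and of dye bias in the stress list were chosen before.

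Of the 80 genes changed by Congo Red, 21 of the 47 higher and 21 of the 33 lower belong to no list. Higher genes among them were PRY2 at 1.37, TOH1 at 1.16, the arginase gene CAR1 at 0.87 and the reading frames YBR071W at 1.22 and YNL058C at 1.13. Lower genes included OPT1 and PTR2, which code for peptide transporters, at -0.81 and -0.68, and NCE102 and LSP1, which code for eisosome proteins of the plasma membrane, at -0.80 and -0.79. The neighbouring dehydrogenase genes BDH1 and BDH2 were at -0.83 and -0.85, the flavohaemoglobin gene YHB1 at -0.67 and the fatty acid activation gene FAA4 at -0.70. DDR48 at 0.92 and YMR173W-A at 0.94 have reading frames that overlap, so their values are not separate evidence.

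Genes with empty cells were not tested. Values on 2 or 3 arrays were present for 1247 reading frames. Of those with a value in each dye orientation, 10 had a mean of at least 1 log unit with a single sign, 7 above 0 and 3 below. PRM10, a membrane protein gene, was at 0.46, 2.03 and 2.11 on arrays 1, 3 and 4, and the proline oxidase gene PUT1 at 1.19 and 1.57 on arrays 3 and 4. The catalase gene CTT1, a general stress gene, was at -1.07, -2.21 and -0.75 on arrays 2, 3 and 4, and the vacuolar aminopeptidase gene APE1 at -1.34, -2.34 and -0.77. More than 2 log units from the median of the other 3 arrays lay 4, 5, 24 and 5 reading frames on arrays 1 to 4. On array 3 these include the mannosyltransferase gene PMT6, at -0.96 against 1.83, 2.49 and 1.08 on arrays 1, 2 and 4, and LRG1 at -1.08.

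The general stress list had a shift of -0.35 with Congo Red (adjusted p = 0.00273; adjusted p = 0.843 with an estimated correlation), and 5 of its 25 members fell. For the list as a whole an offset of the arrays below 0 is argued against, since its median was still -0.20 after each array was centred. The shift against all other genes cannot change with centring. Of the 5 members that fell, SOL4 alone was called after centring, so an offset is not excluded for the calls of the others. Dye bias is argued against, since the highest of the 4 centred array medians was -0.15, so all 4 lay below 0. Untreated cultures nearer to glucose exhaustion might also leave stress genes higher in the untreated RNA. The tricarboxylic acid cycle list, which would then be lower with Congo Red, had a shift of 0.18 that was not called, so this cannot be told apart from a response to Congo Red, which stays a hypothesis.

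The 11 rows of Ty gag reading frames, from retrotransposons with near-identical copies, had medians of 1.21 and 1.69 on arrays 1 and 2 and of -0.25 and -0.03 on arrays 3 and 4. The contrast of arrays 1 and 2 against 3 and 4 had a median of 0.06 in the 12 pol rows. Single pol rows ran from -0.22 (YCL019W) to 1.36 (YML045W). All 11 gag rows were among the 30 of 3080 reading frames where that contrast was largest in size, with a median of 1.64. Dye bias is argued against by a median dye contrast of -0.22, and a defect of 1 array by the median differences within pairs, -0.36 for array 1 minus array 2 and -0.14 for array 3 minus array 4; single rows differed more, but the lowest values on arrays 1 and 2, 0.81 and 1.38, lay above the highest on arrays 3 and 4, -0.08 and 0.52. The rows may differ because arrays 1 and 2 share a culture: across all genes this contrast had an SD 1.40 times that of arrays 1 and 4 against 2 and 3, though a MAD only 1.12 times as large, and a shared day of hybridisation would give the same.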
